A study of Homo sapiens with 2 samples.

How the data were processed

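By the sample labels, which are open to doubt as described below, conditioned media of a human pancreatic cancer cell line were profiled on glass antibody arrays. These carry 507 capture antibodies to cytokines, growth factors, receptors and other proteins. Per the labels' protocols, cells were grown in medium with 10% fetal bovine serum and transfected with a control siRNA (siNC) or an siRNA against JAG1 (siJAG1). The medium was collected after 48 h, 100 µL was incubated on the array for 2 h, and bound protein was read with Cy3-coupled streptavidin. There was 1 array per group, so no p-value, no standard deviation and no test between groups is given here, and every statement compares these 2 arrays and not the conditions in general.

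Each sample came with a sheet that gives, per the file headers, a signal intensity and a relative expression for each antibody. The unit of the signal intensity is not given here, and whether it rises in proportion to protein was not tested. Folds below therefore compare readings and not amounts of protein. The deposited relative expression is a ratio: the values show that the authors took the signal minus a baseline over the positive control mean minus that baseline, so the positive controls stand at 1. The baseline solved from the values was 33619 on the array labelled siNC and 33644 on the array labelled siJAG1, which is 569 and 534 units below the negative mean listed in the same sheets. The series value table holds the same ratio values as the authors' sheets, rounded, as deposited. Scanner, software and any other background step are not given in the sources used here. The sheets also list 3 rows named Positive 2a, 2b and 2c among the antibodies, which were left out. Their relative expression ranged from 0.0161 to 0.0276, close to the 0.0240 and 0.0213 that the negative means would have, although positive controls are set to 1.

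A further sheet of single spots came with both samples. The 2 copies were identical, and their 4 value columns are headed BX3mir-124, BX3_NC, Panc1_mir-124 and Panc1_NC, none of which is a label of this study. These 4 columns were assigned to no sample, and no level or fold given here comes from them. They were read to check whether the sample sheets are means of these columns. For antibodies of the wider set described next, the single spots were also read by eye, and for those called in it they were compared with its floor of 0.2. The pair of spots of Activin B lay on both sides of that floor, so the call of Activin B is doubtful. For all 507 antibodies the signal labelled siNC equalled the mean of the pair of spots in the column headed Panc1_NC, and for all 507 the signal labelled siJAG1 equalled that in the column headed BX3_NC (tolerance 1e-06). The sheet's row and column numbers gave the print layout. Because the columns carry other names, the planned precision from duplicate spots is not given. Apart from the comparison with the floor of 0.2, the spread of the spot pairs was left unused for that reason, although their means equal the values. The error of each value was therefore not estimated here.

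The analysis plan was fixed before the data were examined. It provided that a single, already normalized value per antibody would be used as it stands, without the spot rule. The main value is thus the deposited relative expression, and the ratio is the array labelled siJAG1 over the array labelled siNC, on the log2 scale with no pseudocount. The plan's first choices for detection, against the spread of negative or blank spots or of local background, needed single spots and were not run. Its last choice, 1.5 times background, was used with the negative mean as background. An antibody thus counted as detected on an array when its signal was at least 1.5 times the negative mean. That is a relative expression of 0.744 on the array labelled siNC and 0.704 on the array labelled siJAG1. It was called higher or lower when it was detected on at least 1 array and differed by at least 1.5-fold. This limit is strict, because the positive controls themselves stood only at 1.68 and 1.72 times the negative mean. A wider set, added after seeing the data, took antibodies at or above a relative expression of 0.2 on at least 1 array. In both sets, where 1 array lay below 0.2 the fold is given against a floor of 0.2 and written as "at least". These bounds hold only for the authors' baseline and leave out the error of the values, which was not estimated.

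The text names up to 12 antibodies called in each direction with the largest folds, up to 4 detected members per list with the highest mean relative expression, and the 5 antibodies with the highest mean. Other members of the wider set, and dim antibodies given as single values, were named after their values were seen. The 27 lists of proteins were fixed beforehand and matched to the array by name; 316 of the 507 antibodies belong to at least 1 list. Where a list had at least 3 members in a set, its median log2 ratio was placed among 10000 random lists of the same size. Each member was replaced by 1 of the 10 antibodies of that set nearest in mean level, itself included. Members of the list could thus be drawn, also repeatedly, which can pull the percentile toward the middle. Alternatives were no scaling, division by the array's median or total, no background subtraction, subtraction of the listed negative mean with a floor of 1 signal unit, detection on both arrays, no detection limit, a 2-fold limit and the series value table. Quantile normalization, a floor of 0.1 and scaling to the antibodies with a mean of at least 0.5 were added after seeing the data. Scripts used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Both calling steps were tested on simulated data made from the levels of the array labelled siNC with an assumed noise of 0.05 (SD, log2). Because the true noise was not estimated, this checks the computation and not the error of the calls. With the detection limit, which 10 antibodies pass on that array, 5 of 5 changed antibodies were recovered at 2-fold and 5 of 5 at 4-fold. With the floor of 0.2, which 33 pass, 9 of 10 were recovered at each of these folds, and 0 false calls were made in either step.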

Results

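Conditioned medium of pancreatic cancer cells was compared between a culture labelled siNC (control siRNA) and a culture labelled siJAG1 (siRNA against JAG1, which encodes the Notch ligand Jagged 1), with 1 antibody array each. By its title, the study asked which secreted cytokines differ after JAG1 RNA interference. The labels of the 2 arrays are open to doubt. For all 507 antibodies, the signal labelled siNC was the mean of the spots in a column headed Panc1_NC, and the signal labelled siJAG1 was the mean of the spots in a column headed BX3_NC. Panc1 is the name of a pancreatic cancer cell line other than the one in the sample titles. Neither heading names JAG1, and both end in NC, as the control label siNC does. If the headings were right and NC meant a control there too, no knockdown would be compared. The arrays are therefore called the siNC-labelled and the siJAG1-labelled array, and each direction below rests on those labels. The array holds 0 antibodies to Jagged 1, so the target of the siRNA was not measured.

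Most of the 507 antibodies read near background on both arrays. The median signal was 34827 on the siNC-labelled and 34392 on the siJAG1-labelled array, against negative means of 34188 and 34178 and positive control means of 57374 and 58664. In relative expression, where the positive controls are 1, the medians were 0.0509 and 0.0299, and 468 antibodies (92.3%) stayed below 0.2 on both arrays. At least 0.2 was reached by 33 antibodies on the siNC-labelled array, 23 on the siJAG1-labelled array and 17 on both. By the stricter detection limit, 10 and 6 antibodies were detected, and 0 on both. Across all antibodies the arrays correlated with a Pearson r of 0.616 and a Spearman rho of 0.209; antibodies are not independent replicates, so these values describe the 2 arrays only. Ratios of dim antibodies varied with place on the slide and with the baseline. Among the 478 antibodies with a mean below 0.2, the median log2 ratio was -1.10 in print columns 1 to 5 and 0.41 in columns 26 to 30. Over all antibodies it was -0.78 as reported, -0.05 without background subtraction and -1.92 with the negative mean subtracted.

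Lipocalin-2, an iron-siderophore binding protein, was higher on the siJAG1-labelled array. Its relative expression was 0.965, against 0.0620 on the siNC-labelled array, a level at least 4.82-fold higher with the authors' baseline. Progranulin, a secreted growth factor precursor, stood at 0.713 against 0.0669, at least 3.57-fold higher, and the tyrosine kinase Csk stood at 0.746 against 0.364, which is 2.05-fold. Lower on the siJAG1-labelled array were IGFBP-7, GDF-15, interleukin-1 alpha, MCP-1, MIP 2, IL-8, the urokinase-type plasminogen activator uPA and, except when each array was divided by its median, IGFBP-2. In all, 3 of the 16 detected antibodies were called higher, 8 lower and 5 neither. With 1 array per group and no error for the values, none of these differences has a replicate check. The calls of IL-8, uPA and IGFBP-2 were lost when each array was divided by its median, those of uPA and IGFBP-2 also by its total. That of IGFBP-2 was also lost without scaling, after quantile normalization and after scaling to antibodies with a mean of at least 0.5. Without background subtraction, those of Progranulin, Csk, MIP 2, IL-8, uPA and IGFBP-2 were lost. That setting leaves little room for any call, because the positive controls were only 1.68 and 1.72 times the negative mean. Folds given as "at least" hold only for the authors' baseline: without background subtraction the log2 ratios were 0.69 for Lipocalin-2, 0.52 for Progranulin, -0.77 for IGFBP-7, -0.69 for GDF-15, -0.60 for interleukin-1 alpha and -0.60 for MCP-1. The split between higher and lower moved with the scaling: it was 6 against 5 when each array was divided by its median, 6 against 6 when divided by its total and 5 against 7 after quantile normalization. Division by the median raised the median log2 ratio of all antibodies by 0.77, from -0.78 to -0.01. Each array's median is the level of an antibody near background, so this scaling shifts bright antibodies by a difference measured on dim ones. The 16 antibodies with a mean of at least 0.5 had a median log2 ratio of 0.01, with values from -5.27 to 3.96. The 468 below 0.2 on both arrays had a median of -0.77. As a set, the bright antibodies thus did not share the shift that this scaling corrects. Whether bright antibodies should have equal medians on both arrays is not known, so neither scaling is shown to be right for them.

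**Figure D1:**
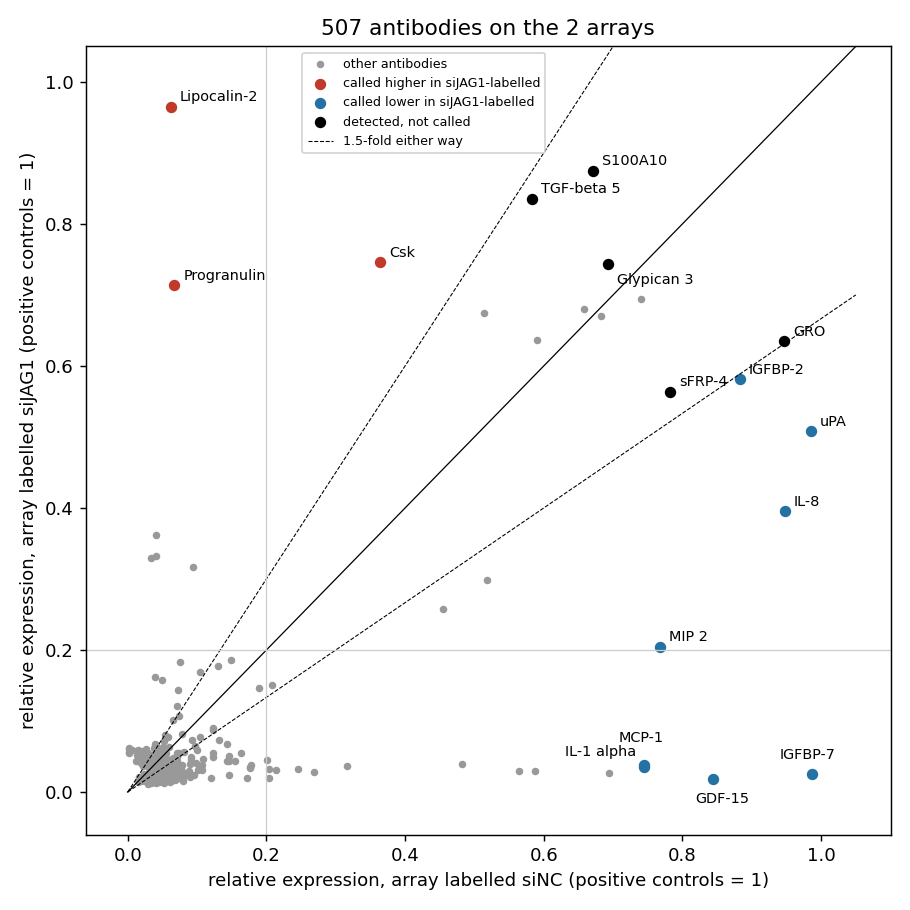
Relative expression of 507 antibodies on the siJAG1-labelled array (vertical axis) against the siNC-labelled array (horizontal axis), with positive controls at 1, 1 point per antibody and 1 array per label. Labelled points are the 16 detected antibodies, dashed lines mark a 1.5-fold ratio and grey lines a level of 0.2; Lipocalin-2 and Progranulin lie at the upper left, and 8 antibodies called lower lie below the lower dashed line, of which IGFBP-2 crosses to the other side of equality when each array is divided by its median.

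Chemokines that attract neutrophils had the most detected antibodies of the 27 lists. Of 7 measured CXC chemokines with an ELR motif, 3 were detected, 2 were called lower and 0 higher. IL-8 (CXCL8) stood at 0.948 on the siNC-labelled and 0.396 on the siJAG1-labelled array, 2.39-fold lower on the latter, with a log2 ratio of -1.26 that was -0.49 and below the size limit when each array was divided by its median. MIP 2 (CXCL2) stood at 0.767 and 0.205, 3.75-fold lower. The log2 ratio of MIP 2 was -1.91 as reported, -1.14 with division by the median and -1.08 after quantile normalization. Without background subtraction it was -0.45, below the size limit. GRO, an antibody to the CXCL1 to CXCL3 group, stood at 0.947 and 0.635, a 1.49-fold difference that missed the size limit. Its log2 ratio of -0.58 became 0.19 when each array was divided by its median, and -0.59, a call, when the negative mean was subtracted. The antibody to CXCL1 alone, GRO-a, was dim on both arrays at 0.0691 and 0.0193. The list's median log2 ratio of -1.26 lay at percentile 11.9 of random lists of 3 detected antibodies, which is not at an extreme. The random lists could hold the list's own members, which limits how extreme this percentile can be. Among 23 CC chemokines the monocyte attractant MCP-1 (CCL2) was the 1 detected, at 0.744 and 0.0353, at least 3.72-fold lower on the siJAG1-labelled array. RANTES (CCL5) reached 0.204 on the siNC-labelled array and 0.0194 on the other. The other 10 CXC, CX3C and XC chemokines stayed at or below 0.0815.

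In the interleukin-1 family, interleukin-1 alpha, an alarm cytokine of epithelial cells, was the 1 detected antibody of 9, at 0.745 against 0.0374, at least 3.72-fold lower on the siJAG1-labelled array. Of 10 antibodies to the interleukin-10 family and interferons, IL-29 alone reached 0.2, at 0.269 against 0.0281. The 9 antibodies to interleukin-6 family cytokines peaked at 0.0785, the 13 to common gamma chain and T helper cytokines at 0.0863, and the 6 to interleukin-17 ligands at 0.0827. IL-6 itself stood at 0.0696 and 0.0188. Of 8 colony stimulating and haematopoietic factors, thrombopoietin reached 0.2, at 0.454 and 0.258, 1.76-fold lower on the siJAG1-labelled array. It was not detected by the strict limit, and its direction turned under quantile normalization.

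In the insulin-like growth factor system, 2 of 11 antibodies were detected, and both were called lower. IGFBP-7, a secreted binding protein, stood at 0.987 against 0.0255, at least 4.94-fold lower on the siJAG1-labelled array with the authors' baseline. IGFBP-2 stood at 0.883 and 0.581, 1.52-fold lower, just past the limit; its direction turned when each array was divided by its median. IGFBP-6 at 0.204 against 0.0327 and the IGF-II receptor at 0.245 against 0.0323 reached 0.2 on the siNC-labelled array only. Each was printed directly beside an antibody bright on that array, IGFBP-6 beside IGFBP-7 and the IGF-II receptor beside interleukin-1 alpha at 0.745. Stray signal was not tested for either, so their place in the wider set and in this list's percentile is open to doubt. Of 25 TGF-beta superfamily antibodies, 2 were detected. The stress-responsive cytokine GDF-15 was called lower, at 0.844 against 0.0177, at least 4.22-fold with the authors' baseline, and TGF-beta 5 was not called, at 0.583 against 0.835. Its log2 ratio of 0.52 passed the size limit without scaling at 0.59, with division by the median at 1.29, with division by the total, and after quantile normalization at 0.97. The name TGF-beta 5 matched 0 human gene symbols or synonyms in the gene table used here. Which human protein this antibody read is therefore not known, and the list's medians and percentile include it. Latent TGF-beta binding protein 1 stood at 0.483 against 0.0395, at least 2.41-fold lower in the wider set. Activin B stood at 0.0945 against 0.317, a doubtful value because its pair of spots lay on both sides of 0.2.

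Of 18 Wnt pathway antibodies, the secreted antagonist sFRP-4 was detected at 0.782 and 0.564 and not called, with a log2 ratio of -0.47 that turned to 0.30 with division by the median and 0.11 by the total. Dkk-1 stood at 0.518 and 0.298, 1.74-fold lower on the siJAG1-labelled array in the wider set and level under quantile normalization. Among 20 antibodies to VEGF and PDGF families and angiopoietins, 0 were detected by the strict limit. The lymphangiogenic factors VEGF-C and VEGF-D stood at 0.588 and 0.565 on the siNC-labelled array and at 0.0290 and 0.0302 on the other, at least 2.94-fold and 2.82-fold lower. Without background subtraction their log2 ratios of -0.50 and -0.48 missed the size limit. Endostatin stood at 0.513 and 0.674. VEGF itself was dim at 0.0577 and 0.0382. Of 16 TNF superfamily ligands, EDA-A2 stood at 0.695 against 0.0272, at least 3.47-fold lower, and TRAIL at 0.214 against 0.0309. TIMP-1, an inhibitor of matrix metalloproteinases, stood at 0.683 and 0.670 as the 1 of 4 TIMPs above 0.2, and 17 matrix metalloproteinases stayed at or below 0.143. uPA, a serine protease that activates plasminogen, stood at 0.985 and 0.508, 1.94-fold lower on the siJAG1-labelled array, with a log2 ratio of -0.96 that was -0.19 with division by the median and -0.38 by the total, both below the size limit. Of 17 adhesion molecules, ICAM-2 stood at 0.590 and 0.637 and ALCAM at 0.0408 and 0.333, the latter at least 1.66-fold higher on the siJAG1-labelled array.

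**Figure D2:**
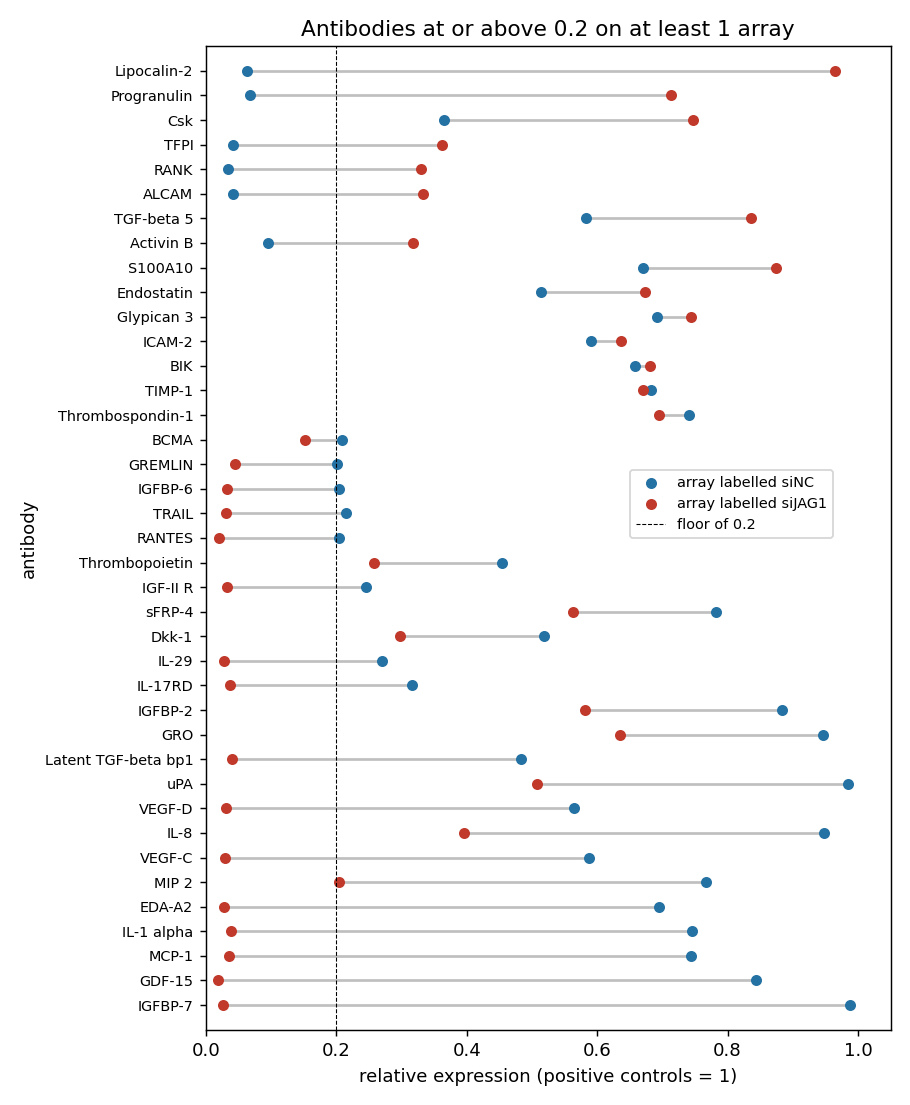
Relative expression (horizontal axis, positive controls at 1) of the 39 antibodies at or above 0.2 on at least 1 array, with a blue point for the siNC-labelled and a red point for the siJAG1-labelled array, ordered by the difference between them. IGFBP-7, with 0.987 and 0.0255, lies at the bottom, Lipocalin-2, with 0.0620 and 0.965, at the top, and the points of TIMP-1 nearly coincide at this scaling; each point is 1 array without error.

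In the wider set of 39 antibodies, 7 were higher on the siJAG1-labelled array by at least 1.5-fold, 15 lower and 17 neither. The split was 15 against 10 when each array was divided by its median, 13 against 11 by its total and 10 against 11 after quantile normalization. Without background subtraction it was 1 against 4, and only the calls of Lipocalin-2, IGFBP-7, GDF-15, interleukin-1 alpha and MCP-1 were kept. With positive controls at only 1.68 and 1.72 times the negative mean, most losses in that setting follow from its small range. Division by the median or the total took Dkk-1 and thrombopoietin below the size limit and TGF-beta 5, S100A10, Glypican 3, endostatin, ICAM-2 and BIK above it, and division by the median also TIMP-1 and thrombospondin-1. Besides the 3 named above, the higher ones were TFPI, a coagulation inhibitor, at 0.361 against 0.0410, the receptor RANK at 0.329 against 0.0336, ALCAM and Activin B. IL-17RD, at 0.317 against 0.0371, was among the lower ones. It was printed diagonally next to IL-8, at 0.948 on the siNC-labelled array, and stray signal was not tested for it.

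Lists that stand for other sources of protein were compared in the same way. The 16 leukocyte surface receptors and the 15 chemokine receptors stand for white blood cells, and peaked at 0.0963 and 0.155. The 11 proteins that bovine serum in the medium could bring had 3 members above 0.2: thrombospondin-1 at 0.740 and 0.694, endostatin, and latent TGF-beta binding protein 1, which is also in the TGF-beta list. Of 8 intracellular proteins, S100A10, the annexin A2 partner, was detected at 0.671 and 0.875 and not called, though its log2 ratio of 0.38 was 1.15 with division by the median. Csk, called higher at 0.364 and 0.746, and the pro-apoptotic protein BIK, at 0.659 and 0.681, also act inside cells but are not in that list. Glypican 3, a heparan sulfate proteoglycan, stood at 0.692 and 0.743, with a log2 ratio of 0.10 that was 0.87 with division by the median. The lists without a member above 0.2 also include 12 EGF family ligands with a maximum of 0.107, 20 FGF family antibodies with 0.0804, 8 neurotrophins and GDNF family ligands with 0.0989, 7 adipokines and hormones with 0.0555 and 4 Toll-like receptors with 0.0730. For the Notch pathway the array holds 1 antibody, to the non-canonical ligand Pref-1 (DLK1), which read 0.0313 and 0.0146. In lists with at least 3 members in the wider set, the median log2 ratio lay at percentile 10.2 for ELR chemokines, 17.4 for the insulin-like growth factor system, 34.6 for VEGF and PDGF families and angiopoietins, 44.6 for serum proteins and 48.4 for the TGF-beta superfamily, none of them at an extreme. Random lists that can hold the list's own members limit how extreme these percentiles can be.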

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

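Quantile normalization, scaling to antibodies with a mean of at least 0.5, the floors of 0.2 and 0.1 and all settings of the wider set were chosen after seeing the data. Of the 11 calls, 0 became a call in the other direction under the other scalings, backgrounds and value table, but the split moved. From 3 higher and 8 lower on the siJAG1-labelled array, division by the array median gave 6 and 5 with 8 of the 11 calls kept, division by the total 6 and 6 with 9 kept, and quantile normalization 5 and 7 with 10 kept. Without background subtraction there were 1 and 4. Detection on both arrays left 0 and 0, because 0 antibodies were detected on both, and no detection limit gave 48 and 296. The floors gave 7 and 15 at 0.2 and 11 and 27 at 0.1, and at 0.2 division by the median gave 15 and 10, by the total 13 and 11, and no background subtraction 1 and 4 with 5 of 22 calls kept. The median log2 ratio of detected ELR chemokines was -1.26 as reported, -0.49 with division by the median and -0.40 without background subtraction. Without background subtraction the TGF-beta list was at -0.26 in place of -2.53 and the insulin-like growth factor list at -0.49 in place of -2.94; with dim members at the floor of 0.2 these were -0.78 and -1.45. The detected part of the intracellular list, S100A10 alone, was at 0.38 as reported, 1.15 with division by the median, 0.96 by the total and 0.66 after quantile normalization. IGFBP-2 was at -0.60 as reported and 0.16 with division by the median, and its call was also lost without scaling, after quantile normalization and after scaling to antibodies with a mean of at least 0.5. Under quantile normalization thrombopoietin was at 0.27 in place of -0.82 and Dkk-1 at 0 in place of -0.80. Beyond what the construction of a setting shows, the cause of each move was not tested. The planned normexp, offset, single-spot, spot rule and duplicate-spot steps were not run, because no single-spot column carries a name of this study, and scaling to positive controls is the reported value itself. No paired analysis was possible because each group has 1 array. Signal over background limits the data: the positive controls were 1.68 and 1.72 times the negative mean. Without background subtraction, only a change from near the positive controls to near background could therefore pass 1.5-fold.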

Other observations

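The comparison with single-spot columns, the search for a Jagged 1 antibody, the tests by print column and those of printed neighbours were chosen after their results were seen. The test of an additive offset was fixed before its value was seen, but after the levels were known and in place of an earlier test of that explanation. The earlier test used antibodies at or above 0.5 on both arrays and had gone with an additive offset. It was replaced because that selection removes antibodies that differ. The verdict on an additive offset thus depends on the test chosen.

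Both antibodies to TNFSF15 were dim, at 0.0426 on the siNC-labelled and 0.0229 on the siJAG1-labelled array for the one named TL1A, and at 0.0584 and 0.0432 for the one named VEGI. The antibody named TGF-beta 5 was detected on the siJAG1-labelled array, although 0 human gene symbols or synonyms read TGFB5 in the gene table used here.

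Antibodies bright on one array and dim on the other form the first pattern. Under 0.1 on the siJAG1-labelled array and at or above 0.5 on the other were 7 antibodies, and 2 showed the opposite. Printed neighbours were examined for these 9 antibodies only, not for the other members of the wider set. Stray signal from neighbouring spots is argued against as the source of the whole pattern, because 5 of these 9 had no positive control and no antibody at or above 0.5 printed directly beside them; it stays open for the other 4, of which 2, interleukin-1 alpha and VEGF-D, adjoined a brighter antibody and 2, IGFBP-7 and VEGF-C, one slightly less bright. JAG1 knockdown may underlie the pattern, but the array holds 0 antibodies to Jagged 1. A candidate explanation is that the media came from 2 cell lines or cultures, since all 507 values of each array equal means of a column with another heading; whether those headings or the sample labels are right cannot be told apart from the files.

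The second pattern is the lower reading of dim antibodies on the siJAG1-labelled array: the median log2 ratio of the 478 antibodies with a mean relative expression below 0.2 was -0.78, a value that depends on the authors' unexplained baseline. One multiplicative factor as the only source is argued against, because the median in print columns 16 to 30 lay 0.69 above that in columns 1 to 15. The bootstrap standard error over antibodies was 0.08. A factor combined with a trend over the slide would give such a gap too, so it stays open. An earlier comparison by level could not decide: the median log2 ratio was -0.88 in the brighter 239 and -0.69 in the dimmer 239. The later test went against a constant additive offset as the only source, though the earlier one had gone with it. The median difference in relative expression was -0.0317 in the brighter 239 and -0.0140 in the dimmer 239. The gap was -0.0178, with a standard error of 0.00295. A candidate explanation is a background that varies over the slide: the median difference was -0.0221 in columns 1 to 5 and 0.0122 in columns 26 to 30, and the medians of 6 blocks of 5 columns spanned 0.0395, against at most 0.0159 in 1000 shuffles of columns within print rows. On the siJAG1-labelled array the block medians rose at each step, from 0.0205 in columns 1 to 5 to 0.0463 in columns 26 to 30. On the siNC-labelled array they rose from 0.0440 in columns 1 to 5 to 0.0566 in columns 16 to 20, and ended at 0.0375 in columns 26 to 30. Levels thus varied over the columns on both arrays. Whether any of the difference is biological was not tested.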
